A study of Drosophila melanogaster with 2 samples.

How the data were processed

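Total RNA (about 1 µg) of sorted type II neuroblast lineages was enriched for polyA RNA and made into strand-specific libraries with dUTP in the second strand, per the labels' protocols. Flies laid eggs for 24 h and were kept for 5 days at 25 °C before larval brains were dissected. The wild type flies carried UAS-CD8::GFP (strain w1118), and the knockdown flies carried UAS-CD8::GFP with the osa RNAi line 7810 of the Vienna Drosophila Resource Center. There were 2 groups of 1 library each. The genotype label put each library in its group.

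The authors deposited 1 table per library with an FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments of the library), its lower and upper bound and a status for each of 14210 genes, per the file headers. The submitters' processing notes name BWA 0.6.1, TopHat 1.4.1, Cufflinks 1.3.0, HTSeq and DESeq 1.8.3, without saying what each was used for. The genome build and annotation are not given in the sources used here. Chromosome names such as 2LHet and XHet stand in the files, and of the 13575 gene identifiers also present in the BDGP6 annotation, 2297 had the same start or end there, so coordinates are given as in the files, counted from 1, and were not joined to that genome. Whether strand was used in counting is not given in the sources used here, so genes with overlapping loci are uncertain.

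A further table deposited by the authors held DESeq output for 15 genes filtered at a false discovery rate of 0.01, per its file header. Its signal columns, deposited by the authors as mean counts divided by size factors, were whole multiples of 1 step per library for all 30 values (within 0.01), and the implied size factors were 0.795 for wild type and 1.26 for osa RNAi. Its ratio column, the fold deposited by the authors, is wild type over osa RNAi, and its log2 column, also deposited by the authors, is the log2 of that fold. Its p-value and adjusted p-value were taken as the authors deposited them. No test was run on these values.

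No depth is stated in the FPKM tables, but it could be read from the intervals. The bounds lay at FPKM ± 2 × FPKM/√n, and n was whole within 0.02 for 93.6% of 839 wild type genes and 94.1% of 1011 osa RNAi genes with 1 transcript and under 50 reads. The value n was therefore used as the implied reads of a gene. Medians over genes above 0 were 324 implied reads in wild type and 467 in osa RNAi, and the 10 genes with the most reads took 9.61% and 9.9%. The reads are PCR products without molecular identifiers, and the FPKM intervals and the fold intervals built from them cover counting error only.

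Levels were compared as log2(FPKM + 1), osa RNAi minus wild type, a scale that understates the difference of low genes. Where a fold is given with an interval, it is the plain ratio of the FPKM values with a 95% interval from the implied reads. With 1 library per group there was no test between genotypes. A gene was counted as at least 2-fold higher or lower when its difference was at least 1 in size, its mean FPKM was at least 1, its status was OK in both libraries and its deposited intervals did not overlap. A status other than OK left out 21 genes with a mean FPKM of at least 1. A fold against a library listed at 0 was not computed.

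The 26 gene lists, the rule for named genes and the alternatives below, except where marked as added, were fixed before the data were examined. Members with a mean FPKM of at least 1 count as measured. For each of the 23 lists with at least 5 measured members, the median difference was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries, and its 95% interval came from 2000 bootstrap resamples of its members. Medians outside percentiles 2.5 to 97.5 were taken as outside the central 95%. The fixed lists partly share members, such as grh, CycE, dm and pnt. The named genes were osa, a fixed set of lineage and complex genes, all genes of the authors' table, the 12 highest and 12 lowest differences among genes past the 2-fold rule with a mean FPKM of at least 5, and up to 4 members of each list with the largest differences; other list members were named after their values were seen, as examples.

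The 2-fold rule was tested on simulated data with counting noise only, for 6809 genes of this comparison above 0 in both libraries. It passed 0% of unchanged genes, 30.6% of genes at a true 2-fold difference, 95.9% at 3-fold and 98.0% at 4-fold. Genes listed at 0 in 1 library, among them 186 of the 556 higher and 141 of the 485 lower genes, were not simulated. The simulated rates do not cover them. Of 200 unshifted simulated lists, 10 fell outside the central 95%, as did all 50 lists shifted by 0.5. Alternatives were pseudocounts of 0.1 and 5, rescaling by the median ratio or the upper quartile, other FPKM filters, fold thresholds of 1.5 and 3, no requirement on intervals, genes of any status, loci under 500 bp left out, 10 expression bins, list means and a stricter adjusted p of 0.001. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.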

Results

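RNA was measured in 2 libraries from larval brains of Drosophila melanogaster at late larval stage (the third instar), 1 library per genotype. Both came from cells sorted by flow cytometry for strong membrane GFP, driven by worniu-Gal4 with ase-Gal80, a driver pair active in type II neuroblast lineages. Type II neuroblasts are neural stem cells that make neurons through intermediate neural progenitors (INPs). Per the labels, the wild type sort held neuroblasts, INPs and ganglion mother cells with neurons excluded, and the osa RNAi sort held neuroblasts, neuroblast-like reverted cells and INPs. The widths of the deposited FPKM intervals implied 10114559 reads on genes in the wild type library and 15707014 in the osa RNAi library, 1.55 times as many. Of 14210 genes, 7772 were above 0 in wild type and 8314 in osa RNAi. Neither genotype was replicated, so no difference below has a replicate check. Intervals of FPKM values and folds cover counting error only, and intervals of list medians cover the spread over member genes only.

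The comparison asks how transcript levels in type II lineages differ when osa is knocked down, and the series title names the PRDM protein Hamlet (ham) as a target of the SWI/SNF complex. The targeted gene osa (FBgn0261885, 3R from 13513540 to 13544059), which encodes a subunit of this chromatin remodelling complex, stood at 31.3 FPKM in wild type (95% interval 30.3 to 32.3) and at 15.6 FPKM in osa RNAi (15.0 to 16.2). That is a 2.01-fold lower FPKM (1.91 to 2.11) and a difference of −0.96 in log2(FPKM + 1). The ATPase gene brm was at 46.5 and 44.6 FPKM, mor at 52.0 and 52.3, and Snr1 at 149 and 118. Bap170, a subunit of the complex form that lacks Osa, was at 16.4 FPKM in wild type and 31.9 in osa RNAi, 1.94-fold higher (1.81 to 2.09). None of the 12 subunits passed the 2-fold rule on the log2(FPKM + 1) scale, although rescaling the libraries by the median ratio put osa, and no other subunit, past it (−1.004). Their median difference was −0.02 (percentile 29.9 among matched random lists).

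INP transcription factors had the lowest median of the 23 fixed lists with at least 5 measured members. Of 20 measured members, 11 were at least 2-fold lower, 1 was at least 2-fold higher and 8 did not pass the rule. ham (FBgn0045852, 2L from 18762874 to 18787500) was at 49.998 FPKM in wild type (47.8 to 52.1) and 18.0 FPKM in osa RNAi (17.0 to 19.1), a difference of −1.42. Among the temporal factors that INPs express in succession, the Sox gene Dichaete (D) was at 82.3 and 23.8 FPKM and the Pax6 gene eyeless (ey) at 4.95 and 0.828 FPKM, whereas grainyhead (grh) was higher in osa RNAi, at 33.6 and 92.2 FPKM. The zinc-finger gene odd-paired (opa) was at 22.5 FPKM in wild type and listed at 0 in osa RNAi. The homeobox gene homeobrain (hbn) was at 22.5 and 1.49 FPKM, the zinc-finger gene Oaz at 7.04 and 0.292, the bHLH gene tap at 81.4 and 27.2, and Optix at 54.1 and 19.6. The INP gene earmuff (erm) was at 44.7 and 41.8 FPKM with overlapping intervals, asense (ase) at 39.4 and 27.7, and prospero (pros), which promotes cell cycle exit, at 38.0 and 20.6. The median difference of the list was −1.21 (95% interval over members −1.64 to −0.54), at percentile 0 of 10000 random lists matched on expression. In the same libraries the neuronal list had a median of −0.21, the stress list −0.25 and the sex composition list −0.57.

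**Figure D1:**
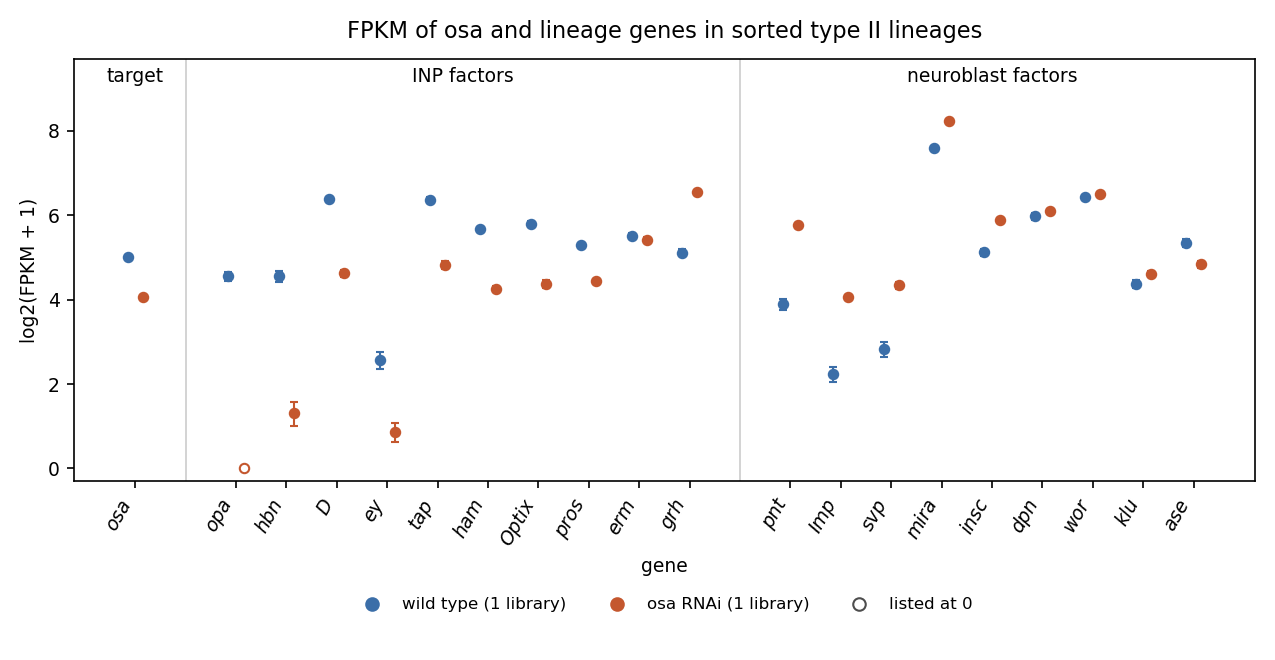
Level of osa, INP factors and neuroblast factors on the vertical axis as log2(FPKM + 1), 1 point per library, with bars for the deposited 95% intervals and an open circle for a gene listed at 0. D, ham and hbn lie lower in osa RNAi (D at 23.8 against 82.3 FPKM), while pnt and grh lie higher (pnt at 53.3 against 13.8 FPKM) and dpn and wor nearly overlap.

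The neuroblast list had a median above 0 in the osa RNAi library. Of 28 measured members, 6 were at least 2-fold higher, 1 (esg) was at least 2-fold lower and 21 did not pass the rule. The ETS factor gene pointed (pnt), whose product acts in type II neuroblasts and INPs, was at 13.8 FPKM in wild type and 53.3 in osa RNAi, 3.85-fold higher (3.48 to 4.26). The RNA-binding protein gene Imp, which marks young neuroblasts, was at 3.71 and 15.6 FPKM, and the orphan nuclear receptor gene seven-up (svp) at 6.06 and 19.2. The temporal regulators Syp (CG17838 in the files, 391 and 729 FPKM) and cas (210 and 400) were also higher, without passing the rule. Young against older neuroblasts was not tested, and no direction of age is drawn from this list. The growth regulator Myc (dm) was at 20.9 and 45.3 FPKM and Cyclin E (CycE) at 30.6 and 66.1, and grh was the remaining member past the rule. Below 2-fold, the cell fate adaptor gene mira was at 192 and 302 FPKM, insc at 33.8 and 58.0, klu at 19.8 and 23.6, tll at 17.0 and 24.9, and btd at 10.8 and 15.8. Other members were lower without passing the rule: ase at 39.4 and 27.7 FPKM, chinmo at 14.5 and 9.08, Sp1 at 62.02 and 45.6, and sna at 15.98 and 11.7. The neuroblast factors deadpan (dpn, 61.97 and 67.3 FPKM) and worniu (wor, 85.2 and 89.3) had overlapping intervals in the libraries. The median of the list was 0.40 (0.18 to 0.85), at percentile 100 of matched random lists. Beside it in these libraries stood the medians below 0 of the neuronal, stress and sex composition lists.

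Of 26 measured genes of asymmetric cell division, 1 was at least 2-fold higher (loco, 5.53 and 12.4 FPKM) and none was lower; staufen (stau) was at 100.4 and 193 FPKM, numb at 60.6 and 61.7, and brat at 83.4 and 88.4. The list median was 0.24 at percentile 97.45, and from 93.31 by the mean of the list to 97.84 with 10 expression bins among the alternatives. Of 30 measured Notch pathway genes, 2 were at least 2-fold lower and 28 did not pass the rule. The lower pair were m6, a Bearded-family gene of the E(spl) complex (13.7 and 2.17 FPKM), and Hey, a Notch target in newborn neurons (11.2 and 2.90 FPKM). The receptor gene Notch (N) was at 20.8 and 25.1 FPKM, its target HLHmgamma at 373 and 429, and Su(H), the DNA-binding factor of the pathway, at 5.45 and 11.4. The Notch list median was −0.02, at percentile 26.1.

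Of 46 neuronal genes in the files, 26 reached a mean of 1 FPKM, and a few of these were lower in osa RNAi: 3 were at least 2-fold lower, 1 was at least 2-fold higher and 22 did not pass the rule. The zinc-finger gene nerfin-1, needed for neuronal differentiation, was at 24.3 FPKM in wild type and 3.24 in osa RNAi, Snap25 at 7.08 and 0.732, and the GABA receptor gene Rdl at 2.70 and 0.545. The SNARE-disassembly gene comt was higher, at 3.22 and 8.45 FPKM, and the pan-neuronal gene elav was at 41.3 and 30.5. The list median of −0.21 lay at percentile 8.27. Of 35 measured cell adhesion and axon guidance genes, 8 were at least 2-fold lower and 1 (Fas1) was at least 2-fold higher. CG3624 was at 72.99 and 18.5 FPKM, the netrin receptor gene unc-5 at 21.8 and 7.32, the Slit receptor gene lea at 16.4 and 6.36, Fas3 at 81.6 and 35.3, and caps at 7.88 and 2.73. Their median of −0.27 lay at percentile 1.32, or 5.35 when genes with overlapping loci were left out.

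Genes of the lists for other cells that a sort of larval brain could hold ranged from high levels to none listed. How specific each gene is to its cell type was not tested, so a high level alone does not show that such cells were present. Genes of the glial list at high levels in both libraries were the glutamate transporter gene Eaat1 (126 and 115.2 FPKM), nrv2 (156 and 121) and Nrx-IV (22.6 and 13.9), and the ferritin gene Fer1HCH of the haemocyte list was at 268 and 202 FPKM. The glial transcription factor gene repo was listed at 0 in wild type and at 0.709 FPKM in osa RNAi. Of 8 measured glial genes, Tret1-1 (7.46 and 16.7 FPKM) and loco were at least 2-fold higher, and gcm (3.45 and 1.05) and CG6126 (2.46 and listed at 0) at least 2-fold lower (median −0.25, percentile 12.6). Of 19 haemocyte and basement membrane genes in the files, 5 were measured (median −0.40, percentile 9.79). Among these 5, 1 was at least 2-fold lower, He, at 4.29 FPKM in wild type and listed at 0 in osa RNAi. Of 8 tracheal and cuticle genes, Gasp was lower, at 9.61 and 3.99 FPKM (median −0.25, percentile 24.75). In the optic lobe and disc list of 15 genes, the proneural gene l(1)sc was higher, at 19.8 and 77.6 FPKM, and ey, Optix and apterous (ap, 7.61 and 0.0313 FPKM) were lower (median 0.13, percentile 70.8). Only 2 genes each were measured in the fat body and salivary gland, muscle and Hox lists, which have 21, 18 and 13 genes in the files. They were Sgs7 (5.13 FPKM and listed at 0) and Lsp1gamma (3.84 and 2.70), Zasp66 (listed at 0 and 2.22 FPKM) and Tm1 (97.9 and 77.0), and hth (9.62 and 16.8 FPKM) and exd (27.2 and 27.7).

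Genes of the nucleolus and of ribosome assembly were higher in osa RNAi as a list. Of 33 measured members, 4 were at least 2-fold higher and none was lower. RpI1, the large subunit of RNA polymerase I, was at 16.8 FPKM in wild type and 40.2 in osa RNAi, CG7728 at 8.08 and 18.7, U3-55K at 9.74 and 20.9, and dm was again among them. The list median was 0.45 (0.34 to 0.69), at percentile 100, in the same libraries in which the stress list had a median of −0.25 and the sex composition list −0.57. In contrast, none of 77 cytosolic ribosomal protein genes passed the rule, with a median of −0.05 at percentile 7.78. Among 51 cell cycle genes, Cyclin B3 (CycB3, 54.4 and 164 FPKM), CycE and Cdk4 (7.97 and 17.0) were at least 2-fold higher. The Cyclin E/Cdk2 inhibitor gene dacapo (dap) was lower, at 21.8 and 7.77 FPKM. Their median of 0.19 lay at percentile 97.7, and at 94.74 without genes that overlap another locus.

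Genes of oxidative phosphorylation had a narrow range of differences, with none of 38 measured members past the rule. Cytochrome c (Cyt-c-p) was at 349 and 580 FPKM and ND23 of complex I at 177 and 260, and the list median was 0.21 (0.13 to 0.28) at percentile 99.96. Of 15 genes of the glycolysis list, Treh, which splits trehalose, was 3.72-fold higher in osa RNAi (3.34 to 4.16), at 12.7 and 47.1 FPKM. The glycolytic enzyme genes Pfk (6.16 and 12.7 FPKM) and Ald (50.4 and 86.3) did not pass the rule, and the median was 0.11 at percentile 66.4.

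Of 27 heat shock and dissociation stress genes, puc (4.32 and 1.38 FPKM), Gadd45 (2.73 and 0.735) and Hsp67Bc (88.5 and 42.2) were at least 2-fold lower, 24 did not pass the rule and none was higher. The heat shock gene Hsp68 was at 692 and 394 FPKM, and the median was −0.25 at percentile 0.15. Of 7 measured innate immunity genes, 4 were at least 2-fold higher. The antimicrobial peptide genes Drs (6.87 FPKM) and Dpt (3.56 FPKM) were listed at 0 in wild type, CecA2 was at 9.24 and 38.8 FPKM, and AttB at 1.19 and 6.34. The median was 1.74 at percentile 100, with 8.7 to 180 implied reads behind each value above 0 of these 4 genes, and 0.78 with a pseudocount of 5 or 0.96 without genes listed at 0. Equal levels would have given 27 reads of Drs and 18 of Dpt in wild type, where 35.3% of genes with 20 to 40 expected reads and 59.7% with 10 to 20 were listed at 0. Of 7 genes of the sex composition list, dsx (2.05 and 0.459 FPKM) and the male-specific RNA roX2 (44.3 and 21.1) were lower, roX1 was at 321 and 261 FPKM, and the median was −0.57 at percentile 0.67, or 4.07 without overlapping genes.

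The remaining lists had medians within the central 95% of random lists. Of 21 targets of Wnt, Hedgehog, Dpp and EGFR signalling, the EGFR pathway genes pnt, argos (aos, 5.23 and 16.1 FPKM) and kek1 (listed at 0 in wild type and 2.60 FPKM in osa RNAi) were higher, and ci, the Hedgehog effector, was lower at 4.05 and 1.31 FPKM. Their median was −0.08 at percentile 23.9. Of 22 hormonal and temporal regulators, 3 were higher (Imp, svp and Hr39, the last at 0.991 and 3.48 FPKM) and none was lower, with a median of 0.14 at percentile 74.95. Of 14 apoptosis genes, the caspase gene Dcp-1 (9.45 and 21.5 FPKM) and CG6272 (12.2 and 39.3) were higher and the cell death gene skl (6.29 and 2.63) was lower, with a median of 0.09 at percentile 62.6. Of 7 transgene-linked and RNAi pathway genes, the eye pigment transporter gene white (w), a common marker in fly transgenes, was higher at 47.2 and 240 FPKM. Only the knockdown flies carried the RNAi line, so for w transgene content and osa knockdown cannot be told apart. The siRNA-processing gene Dcr-2 was at 451 and 272 FPKM, its partner AGO2 at 37.5 and 42.1, and the list median was 0.07 at percentile 57.9.

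**Figure D2:**
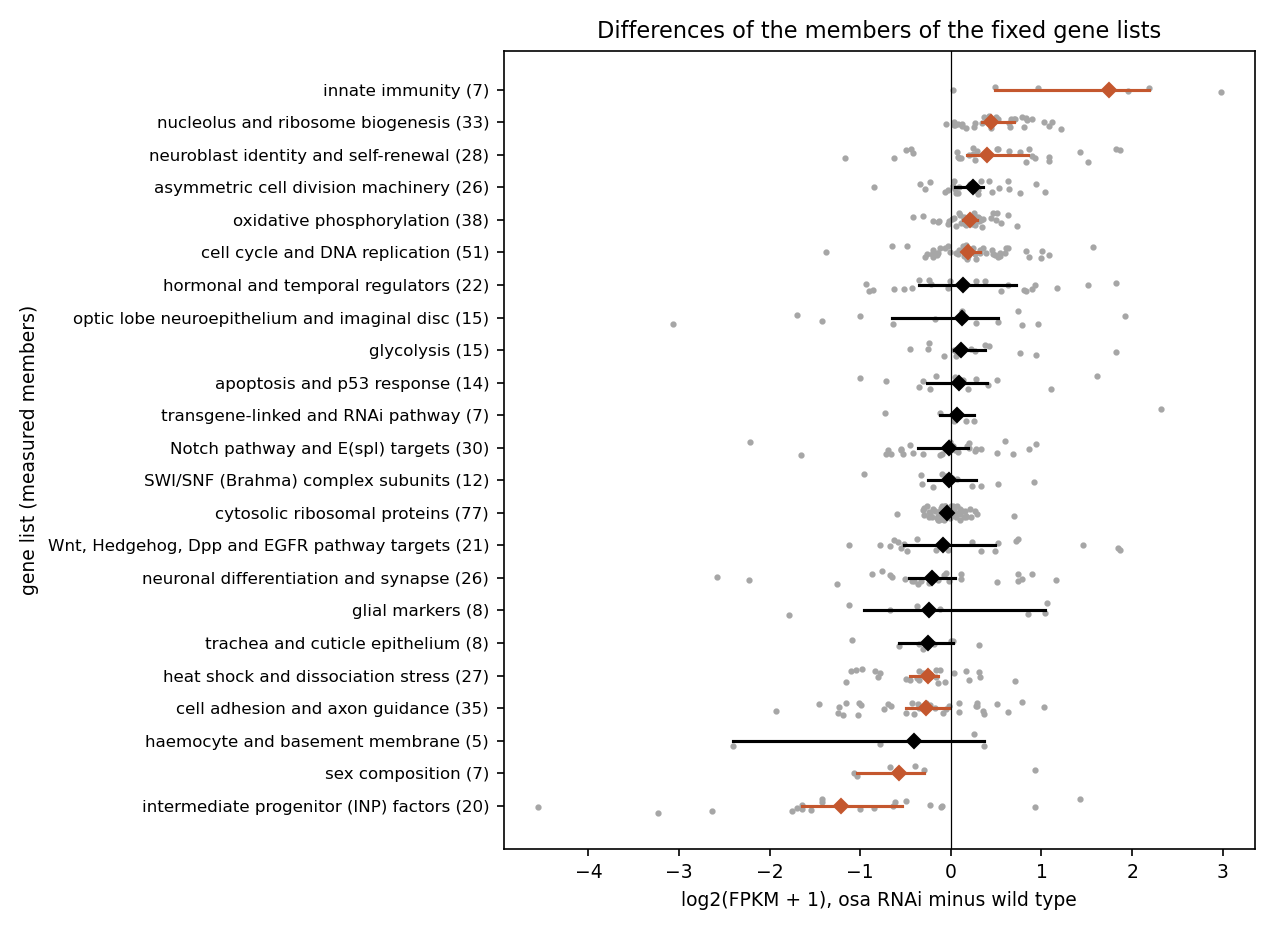
Difference in log2(FPKM + 1), osa RNAi minus wild type, on the horizontal axis for each measured member (grey points) of the 23 lists with at least 5 measured members, with the list median (diamond) and its 95% bootstrap interval over members (line), coloured where the median lies outside the central 95% of matched random lists. INP factors lie lowest (median −1.21), and the nucleolar list (0.45), the neuroblast list (0.40) and the innate immunity list (1.74) lie highest.

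Across 7144 genes with a mean of at least 1 FPKM and an estimate marked OK in both libraries, 556 were at least 2-fold higher and 485 at least 2-fold lower in osa RNAi with intervals apart, 14.6% in all. Among the former, 186 were listed at 0 in wild type, and among the latter, 141 were listed at 0 in osa RNAi. The 12 highest differences with a mean of at least 5 FPKM were, with their FPKM in osa RNAi, IM14 (28.3 FPKM), ltd (25.0), CR43701 (18.7), Rdh (18.2), e(y)2b (17.1), CG32640 (15.3), CG42245 (13.7), CG11686 (12.3), unsRNA:CG10576-a (11.97), Cpr64Ac (11.95), CG7039 (11.8) and CG43150 (11.01 FPKM), all listed at 0 in wild type. The 12 lowest, with FPKM in wild type and osa RNAi, were MED9 (155 and 0.00803 FPKM), opa, CG14933 (18.2 FPKM and listed at 0), wun2 (14.9 and listed at 0), Cpr51A (10.8 and listed at 0), nAcRbeta-64B (18.8 and 0.678), CG15083 (32.6 and 2.09), hbn, CG43117 (46.6 and 4.59), CG3703 (14.03 and 0.798), run (13.5 and 0.796) and sprt (26.9 and 3.10). The locus of MED9 overlaps that of CG42518, which differed the other way (16.6 and 181 FPKM), so how reads were split between them is uncertain. The same holds for 3001 of the 7144 genes whose loci overlap another, among them Rdh, e(y)2b, CG42245 (over MEP-1), CG3703, sprt, w (over kirre), mira, insc, svp, l(1)sc, unc-5 and Dcr-2. The median difference of all these genes was 0.04, and the Pearson correlation of log2(FPKM + 1) across genes, which are not independent replicates, was 0.935.

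A value of 0 was common where few reads were expected. All 13 mitochondrial genes were listed at 0 in both libraries, so 0 in these files is not evidence that a transcript was absent. Of genes for which the other library's level and the depth ratio gave 1 to 10 expected reads, 62.1% were listed at 0 in wild type and 43.0% in osa RNAi. At 80 to 160 expected reads these shares were 1.92% and 3.65%, and at 320 or more they were 0.0499% and 0.0419%. Of the genes named above, opa had 716 implied reads in wild type and ltd 918 in osa RNAi, whereas CR43701 had 9 in osa RNAi.

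**Figure D3:**
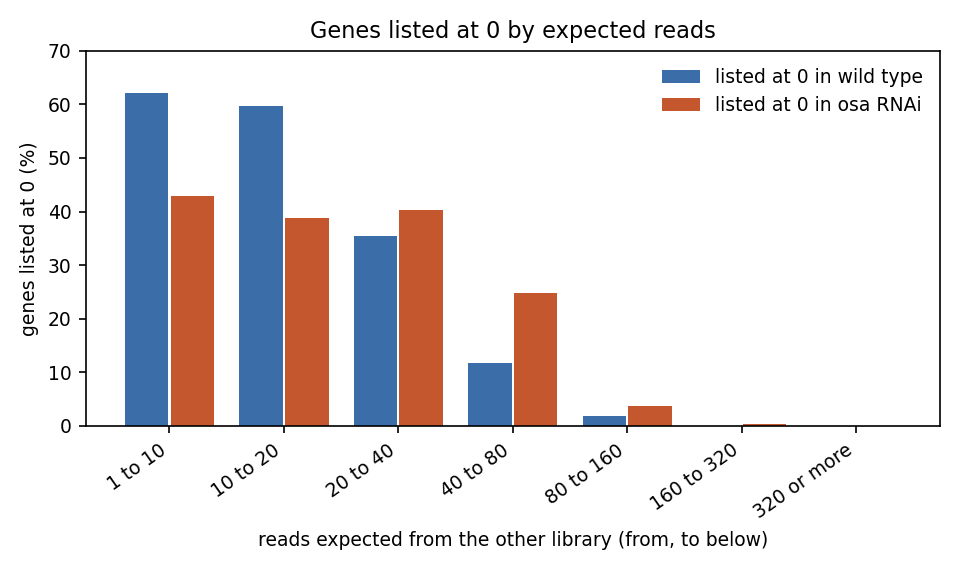
Percent of genes listed at 0 in each library (vertical axis) by the reads expected from the other library's level and the depth ratio (horizontal axis, ranges of expected reads). The share drops from 62.1% in wild type and 43.0% in osa RNAi at 1 to 10 expected reads to under 0.1% at 320 or more.

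The authors' deposited table held 15 genes at a false discovery rate of 0.01, 6 of them higher in osa RNAi and 9 higher in wild type. In the authors' deposited table opa had 820 normalized counts in wild type and 0 in osa RNAi (adjusted p = 3.01e-17), and the phosphatase gene wun2 had 342 and 0 (adjusted p = 2.85e-06). Its other genes higher in wild type were the transcription factor genes run, ap, nerfin-1 and D, the arginine kinase gene Argk (391 and 139 FPKM), sprt and CG3703. The genes higher in osa RNAi in the authors' deposited table were ltd (0 and 700.2 normalized counts, adjusted p = 5.24e-13), w (1580 and 6939, adjusted p = 6.14e-06), Imp (206 and 1328, adjusted p = 0.000525), pnt (372 and 1711, adjusted p = 0.0028), papi (23.9 and 451, adjusted p = 0.00356) and CG17018 (0 and 224, adjusted p = 0.00475). All 15 genes differed in the same direction in FPKM and passed the 2-fold rule there. Counts and FPKM come from the same 2 libraries and these genes were chosen for large differences, so this is no independent check. Sizes were near for Argk (2.74-fold in the authors' counts and 2.82-fold in FPKM) but not for papi (18.9-fold and 4.97-fold). The genes osa and ham were not in the authors' deposited table. Those p-values rest on 1 library per genotype.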

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

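Leaving out genes listed at 0 in either library and leaving out genes with overlapping loci were added after the results were seen; the other alternatives were planned. The lower level of osa and the directions of all 15 genes of the authors' table held under the pseudocounts and rescalings, which could not have reversed them. The INP, neuroblast, nucleolar, oxidative phosphorylation, stress and immunity lists stayed outside the central 95% under every alternative run for them. Medians ran from −1.42 to −0.74 for INP factors, 0.26 to 0.51 for neuroblast genes and 0.78 to 2.06 for immunity genes. For osa, rescaling by the median ratio gave −1.004, past the 2-fold rule, which osa did not pass at a pseudocount of 0.1. A pseudocount of 5 gave −0.82 for osa and 154 genes higher and 109 lower. A mean FPKM of at least 5 gave 261 and 180, a 3-fold threshold 286 and 246, and a 1.5-fold threshold 1219 and 1023, as stricter or looser limits must. Without genes listed at 0 in either library 370 were higher, and without overlapping loci 297 were higher and 274 lower, since fewer genes were counted. The percentile of the cell cycle list was 97.41 with a pseudocount of 0.1 and 94.74 without overlapping loci. That of asymmetric division, 97.45 as reported, was 97.59 with no filter and 97.84 with 10 bins, but 95.92 with a pseudocount of 5 and 93.31 by its mean. The sex composition list was at 2.9 by its mean and 4.07 without overlapping loci, and the adhesion list at 5.35 without them; the cause was not tested. Rescaling by the median ratio moved the cytosolic ribosomal median to −0.0918 and that of all genes from 0.04 to −0.01. The mean of the transgene-linked list was 0.28, and at an adjusted p of 0.001 the authors' table held 7 genes. Medians of the optic lobe, apoptosis, haemocyte, SWI/SNF and signalling lists took either sign across alternatives. Of 544 values for 136 named genes under alternatives, 113 moved by more than their interval, 108 of them under other pseudocounts. No named gene past the 2-fold rule changed direction, an outcome that was fixed in advance. Single genes were run only under the pseudocounts and rescalings. A pseudocount cannot reverse a direction, and rescaling factors of 0.984 to 1.016 are too near 1 to reverse a 2-fold difference. Changes of direction were not counted for named genes that did not pass the rule.

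No paired analysis was possible because each genotype had 1 library and no test was made, and for the same reason no library could be left out. Summing FPKM over the rows of a symbol gave no values, as each symbol has 1 row. Depth limits what can be said of low genes: 59.7% of genes with 10 to 20 expected reads were listed at 0 in wild type and 38.7% in osa RNAi.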

Other observations

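The gene families in this part and all tests in it except the count of flanking genes were chosen after the results had been seen. Of 22 further gene families, 20 had at least 5 measured members, and 7 of these had medians outside the central 95% of matched random lists. Odorant-binding protein genes were lower in osa RNAi, with 5 of 7 measured members past the 2-fold rule (median −1.91, interval over members −1.98 to −0.95, percentile 0). Of these 5, Obp47b, Obp49a, Obp50b and Obp56a were at 2.76 to 3.22 FPKM in wild type, on 17.1 to 42 implied reads, and listed at 0 in osa RNAi. Equal levels would have given 26.5 to 65.2 reads there, a range in which 40.3% (20 to 40 expected reads) or 24.9% (40 to 80) of genes were listed at 0. The members above 0 in both libraries were Obp44a at 163 and 94.1 FPKM, Obp99a at 49.5 and 25.1, and Obp99c at 12.9 and 5.84. Of 5 glutathione S-transferase genes of the E class, which detoxify small molecules, GstE5, GstE7 and GstE8 were lower and GstE6 was higher (median −1.50, percentile 0.555), and the interval over members, −2.04 to 1.42, included 0. Of 5 measured histone genes, 4 of them for variant or replacement histones and 1 (His2B:CG17949) replication-dependent, none passed the rule, with His2Av at 3388 and 2356 FPKM and His3.3B at 1362 and 962 (median −0.50, interval −0.52 to −0.00202, percentile 0.1).

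Of 21 subunits of the vacuolar proton pump, which acidifies lysosomes and other compartments, 5 were at least 2-fold higher and none was lower (median 0.38, percentile 99.6), though the interval over members, −0.05 to 0.63, included 0. VhaM8.9 was at 34.6 FPKM in wild type and 85.3 in osa RNAi, and VhaM9.7-c at 15.4 and 39.5. Mitochondrial ribosomal protein genes had 2 of 72 members at least 2-fold higher and none lower (median 0.21, interval 0.08 to 0.29, percentile 99.9). None of 15 nucleoporin genes passed the rule (median 0.29, interval 0.07 to 0.43, percentile 97.7). Germline and piRNA pathway genes had 7 of 29 members at least 2-fold higher and 2 lower (median 0.46, interval 0.25 to 0.69, percentile 99.7). Among them mael was at 4.59 and 16.2 FPKM, gcl at 1.49 and 8.13, zuc at 1.75 and 6.89, bam at 0.506 and 5.20, and the germ cell helicase gene vas was listed at 0 in wild type and at 3.71 FPKM in osa RNAi. The piRNA gene spn-E, at 9.91 and 4.37 FPKM, and bgcn, at 2.19 and 0.536, were lower.

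The genes opa and wun2 in osa RNAi, and ltd, CG42245 and CG17018 in wild type, were listed at 0 although the other library held 287 to 918 implied reads of each. In the authors' deposited table, whose genes were chosen for large differences, opa, wun2, ltd and CG17018 (4 of 4) had a normalized count of 0 in the same library while run was kept at 12.7 in osa RNAi and papi at 23.9 in wild type, which argues against few reads set to 0 for these 4, and 4 of the 5 genes overlap no other locus, which argues against reads given to a neighbour. For CG42245, whose locus overlaps MEP-1, MEP-1 was 1.10 times as high in wild type as in osa RNAi (44.97 and 41.0 FPKM), which leaves that route open, as is a loss in the file at 484 expected reads, since CG42245 is not among the 15 genes of that table. Of 10 flanking genes, 1 passed the rule in the same direction. This count cannot decide on a strain difference over several neighbouring genes, since the flanking genes lie at separate loci. A difference in a single gene between the w1118 flies and the RNAi line may also remain. An effect of osa knockdown on these genes was not tested apart from strain and stays open.

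The INP list had a median below 0 and the neuroblast and nucleolar lists had medians above 0, although 21 of 28 neuroblast and 29 of 33 nucleolar genes did not pass the rule. Trends of the difference with expression level and locus length were small (Spearman's rho across genes 0.00973 and −0.00363). The trend was taken as the medians of 20 bins by level and of 20 bins by locus length, subtracted in turn. Its median was −0.0116 at the INP members, 0.0263 at the neuroblast members and 0.047 at the nucleolar members. Each was smaller in size than the nearest bound of that list's interval, which argues against such trends as the cause. Rescaling moved the median of all genes by at most 0.0448, under the nearest interval bound of these lists, 0.179. This argues against an offset between the libraries that most genes share. Both rescalings take the bulk of genes as unchanged, so they cannot test a true change of most genes. The INP median lay −1.002 from the neuronal median (2-sided permutation across 20 and 26 genes, which are not replicates, p = 0.00132). This difference cannot exclude fewer neurons in the osa RNAi sort. Per the labels, neurons were already excluded from the wild type sort, and only 26 of 46 neuronal genes were measured. Of these, nerfin-1, Snap25 and Rdl were at least 2-fold lower, comt was at least 2-fold higher and 22 did not pass the rule. A candidate explanation, not tested, is a sort with more of the neuroblast-like cells that the labels name and fewer INPs or ganglion mother cells. The labels name ganglion mother cells for the wild type sort only. Of the lists, 11 of 20 INP members were at least 2-fold lower and 6 of 28 neuroblast members at least 2-fold higher. The neuroblast genes dpn (61.97 and 67.3 FPKM) and wor (85.2 and 89.3) and the INP gene erm (44.7 and 41.8) had overlapping intervals. A different mix of cells cannot be separated here from different expression within the same cell types or from a difference between single libraries.

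The higher germline and piRNA genes might come from gonad tissue in the dissection, from weak derepression in brain cells or from counting near the listing floor. Of the abundant germline genes nos, piwi, AGO3, vas and aub, 1 (vas) was at least 2-fold higher, and aub at 3.45 and 4.70 FPKM (86 and 192 implied reads) was not. AGO3 (0.833 and 0.683 FPKM) and nos and piwi (listed at 0 in both libraries) had too few reads to count either way. Elsewhere in the list, zpg (1.63 and 5.23 FPKM, 20 and 101 implied reads), bam and gcl were at least 2-fold higher, and 2 members were at least 2-fold lower. These genes cannot decide on gonad tissue, which stays open. The floor was tried in 2 ways: the 18 members with at least 80 implied reads in each library had a median at percentile 96.85, inside the central 95%. After that value was seen, the limit was set on the mean over libraries instead, which does not favour genes present in both, and the 22 members it kept lay at percentile 97.72, outside it. The result thus turns on the limit and leaves the floor open, and derepression with osa RNAi was not tested.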
